A study of Mus musculus with 2 samples.

How the data were processed

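Small RNA from lung tissue of newborn B6NCrl mice was sequenced as microRNA-seq, with a size range under 30 bases per the labels. The labels name 2 biological replicates, from pup 1 and pup 3 of pregnancy 1, each library made from 2 lungs of its pup on postnatal day 0. The labels give both the same donor record and different tissue samples, and the sex was not collected. The samples were treated as 1 group of 2 biological replicates, named by the replicate number in the labels. Gene read numbers of the libraries differed far beyond sampling noise (chi-square of 75.2 per degree of freedom over 374 degrees of freedom), so they were counted as separate libraries. This cannot tell whether they came from different pups, because 2 libraries of 1 animal can also differ by more than sampling noise. That they came from different pups rests on the labels.

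The authors deposited 1 table of read counts per library, with whole-number counts per miRNA gene and no normalization, on the assembly mm10 with the GENCODE M4 annotation per the deposited description of the files. The aligner, the counting program, adapter trimming and filters are not given in the sources used here. Each table has no header and holds the gene identifier and 3 columns of counts. The first count column equals the sum of the others in every gene row, and these were read as reads on the gene's own strand and reads on the opposite strand. The own-strand column, which held 98.2% and 98.0% of the reads on miRNA genes in replicates 1 and 2, was the main measurement. The column was to be taken from a statement of the library's strand or else by the number of reads. No such statement was found, and the larger of the single-strand columns was used, because the either-strand column always holds the most reads.

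The 4 rows that name no gene stayed out of library sizes and tests. Of 8277063 reads in replicate 1 and 10391718 in replicate 2, reads mapped to several places made up 34.6% and 36.7%, unmapped reads 8.49% and 8.69%, reads on no feature 2.18% and 2.41%, and reads on miRNA genes 54.8% and 52.2%, with 0 ambiguous reads. These values are from the own-strand column. Reads on the opposite strand of a miRNA gene have no gene row in it and were taken to be among those on no feature. Reads mapped to several places have a total of their own, so the gene rows were taken to hold reads with a single position. A miRNA encoded by several near-identical genes can therefore be undercounted. Reads on the arms of a precursor were counted together, and each value is for the precursor gene.

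The tables hold 1973 gene identifiers. Of these, 1894 matched GENCODE M21, on GRCm38, the same assembly as mm10, and took symbol, position and host gene from it. The 79 unmatched identifiers held 1 read in all and were kept in the totals. List members were matched by symbol, and members with older symbols through the RefSeq gene table of GRCm38.p6, which gave Mir146 for miR-146a. Members with no matching row were left out. The host of a precursor was a longer gene overlapping it on the same strand, a protein-coding one where there was a choice. The precursor was called exonic where it overlaps an exon of any transcript of its host, intronic otherwise, and intergenic with no host. Precursor sequences from the M21 transcripts were searched for stretches of 20 bases found in another miRNA gene. Such a stretch was found in 923 genes, 69 of them with at least 10 reads in each library.

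Levels were counts per 1000000 reads on miRNA genes (CPM), computed here from the deposited counts. A gene was called detected with at least 10 reads in each library. The 95% interval of a share of reads in 1 library was the exact Clopper-Pearson interval. For a single gene it was at most 0.0676 percentage points wide. The floor for a gene with 0 reads was 3 reads of the library's total. Agreement was measured by Pearson's r and Spearman's rho of log2(CPM + 1) with 1000 bootstrap resamples of genes, by the SD of the log2 ratio, and by the common dispersion of edgeR with an intercept only. Each gene with at least 10 reads in the libraries together was tested with a two-sided exact binomial test of its split of reads against the library totals, with Benjamini-Hochberg adjustment at 0.05 over 375 genes. The quasi-likelihood test of edgeR needs replicates on each side and was not run. List percentiles came from 10000 random lists of the same size.

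The 19 gene lists, the 29 clusters, the tests of the report, the rule for named genes and the alternatives were chosen before the data were examined, apart from leaving out members with shared stretches. Most tests of explanations in the closing section were chosen after the results were seen, as stated there. Named were the 25 genes with the highest mean CPM, the 3 highest members of each list, the highest and lowest member of each cluster described, and the 5 genes on each side with the largest log2 ratio between libraries among those past the test with a mean of at least 100 reads. Muscle miRNAs at 0 reads, the genes given for the opposite strand, and the genes of positional groups were named after their values were seen. For 1 cluster, Mir497 and Mir195, fewer than 2 members had a row and no ratio was computed.

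Alternatives were other read minimums (1, 50 and 100 reads, none, or 1 CPM), pseudocounts of 0.1 and 10, TMM scaling of edgeR, size factors of DESeq2, totals without the most abundant gene, the either-strand column, libraries thinned to equal totals, each replicate left out, precursor copies summed, lists without their most abundant member, random lists from genes with reads, and members with shared stretches left out. The tests were tried on simulated data with the means and library sizes of the 375 tested genes. For replicate 2 against replicate 1, the exact binomial test recovered 68% of 100 genes changed by 1.5-fold and 80% of 100 changed by 3-fold, and called 1.71% of unchanged genes in that mixture. With no gene changed it called 0 genes. The test allows for counting error only. The deposited libraries had a larger spread, with a coefficient of variation of 13.2%, so these rates do not describe the calls made on them. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.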

Results

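Mature microRNAs were profiled by small RNA sequencing in the lungs of newborn mice of the B6NCrl strain, a C57BL/6N substrain, on postnatal day 0. The samples form 1 group of 2 libraries. By the labels each was made from both lungs of a different pup of the same pregnancy, although both carry the same donor record. Replicate 1 held 4532902 reads on miRNA genes and replicate 2 held 5426081. All levels are counts per 1000000 reads on miRNA genes (CPM), given as mean ± SD over the 2 pups. Intervals and detection floors cover counting error only, since reads copied by PCR are not independent molecules. With no second tissue, age or treatment, the design allows a description of the newborn lung, comparisons between miRNA groups within it, and a comparison of the pups.

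Which miRNAs made up the newborn lung profile was addressed first. Mir126a, an endothelial miRNA encoded within Egfl7, was the most abundant gene at 160649 ± 12.4 CPM (SD, n = 2). It was followed by Mir322 at 134487 ± 1567 CPM and by Mir143, a miRNA of smooth muscle and fibroblasts, at 67837 ± 3158 CPM. Mir335, located in an intron of the imprinted gene Mest, reached 57219 ± 987 CPM, and Mirlet7g reached 47802 ± 4922 CPM. Mir126a alone took 16.1% ± 0.0012 of the reads (SD, n = 2), with exact Clopper-Pearson 95% intervals of 16.0302% to 16.0979% in replicate 1 and 16.0349% to 16.0967% in replicate 2. The 10 most abundant genes took 62.1% ± 0.951, the top 25 took 82.2% ± 0.144 and the top 100 took 97.8% ± 0.0196. Reads mapped to several places, 34.6% and 36.7% of all reads in replicates 1 and 2, are in no gene row. The shares and the ranking leave them out, so miRNAs encoded by several near-identical genes can stand too low in both.

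The remaining genes among the 25 most abundant ranged from 37674 ± 4704 CPM for Mir26b to 6737 ± 819 CPM for Mir127. In falling order after Mir26b they were Mir99a at 31605 ± 951 CPM, Mirlet7i at 29478 ± 97.3 CPM, Mir23a at 28307 ± 1470 CPM, Mir23b at 25860 ± 1348 CPM, Mir21a at 25374 ± 1048 CPM and Mir130a at 21644 ± 966 CPM. Mir449a, located in an intron of Cdc20b, a gene of multiciliated cells, stood at 17777 ± 591 CPM. Mir30a, Mir10a, Mir30e, Mirlet7d, Mir30d, Mir429, Mir22, Mir99b, Mir200c, Mir351 and Mir411 completed this set. Of the 1973 miRNA genes measured, 308 had at least 10 reads in each library, which is 15.6%, and 1306 had no read in either. For a gene whose reads have a single position, a count of 0 allows a level of up to 0.662 CPM in replicate 1 and 0.553 CPM in replicate 2. A 20-base stretch found in another miRNA gene was held by 923 genes, 69 of them with at least 10 reads in each library. For such genes a count of 0 can also come from reads mapped to several places, and it sets no such limit. At least 1000 CPM was reached in both libraries by 78 genes, and at least 10000 CPM by 20.

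The leading precursors were placed on the mouse assembly GRCm38 (mm10). Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429 on the plus strand, where the annotation holds an exon of an Egfl7 transcript. Its 73-base precursor reads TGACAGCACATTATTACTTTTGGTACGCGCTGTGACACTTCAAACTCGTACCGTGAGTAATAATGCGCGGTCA, and 728167 and 871743 reads were counted on it in replicates 1 and 2. Mir322 (ENSMUSG00000065418.1) lies between genes on chromosome X from 53054255 to 53054349 on the minus strand. Its 95-base precursor reads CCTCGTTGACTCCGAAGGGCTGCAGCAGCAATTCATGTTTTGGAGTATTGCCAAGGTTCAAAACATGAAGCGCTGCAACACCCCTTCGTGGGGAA, with 614637 and 723726 reads. Mir143 (ENSMUSG00000065445.2) lies between genes on chromosome 18 from 61649196 to 61649258 on the minus strand. Its 63-base precursor reads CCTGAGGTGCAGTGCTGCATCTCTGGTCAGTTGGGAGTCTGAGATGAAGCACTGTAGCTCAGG, with 297377 and 380207 reads.

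The levels of miRNAs known from the cell compartments of the lung were compared next. The endothelial list was the highest, with a summed level of 220167 ± 463 CPM (SD, n = 2) over 8 measured members, of which Mir126a made up 73.0% and Mir23a and Mir23b were the next highest. The smooth muscle and mesenchyme list totalled 90379 ± 3984 CPM, with Mir143 at 75.1% of it, followed by Mir10a at 15932 ± 1251 CPM and Mir214 at 4550 and 3943 CPM in replicates 1 and 2. The lung and airway epithelium list totalled 38465 ± 168 CPM, and all 11 of its members had at least 10 reads in each library. Its highest members belonged to the miR-200 family of epithelial miRNAs, with Mir429 at 11543 ± 541 CPM, Mir200c at 9839 ± 2.14 CPM and Mir200b at 6368 ± 643 CPM. The multiciliated list totalled 22725 ± 95.3 CPM, led by Mir449a at 78.2% of the list, with Mir34c at 4218 ± 475 CPM and Mir34a at 567 ± 14.0 CPM.

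The endothelial list exceeded the epithelial list by 2.52 ± 0.0093 on the log2 scale (SD, n = 2), a ratio of 5.72. Without the most abundant member of each list, this log2 ratio was 1.14, with Mir23a and Mir23b then the highest endothelial members. A stretch found in another miRNA gene is held by 5 of 8 measured endothelial members, and 2 members have no row. Uncounted reads of these can leave both values too low. Without the members that hold the stretch the log2 ratio was 2.07, and it rested on Mir126a, Mir221 and Mir222 at 160649, 456 and 255 CPM. The smooth muscle and mesenchyme list exceeded the epithelial list by 1.23 ± 0.070, a ratio of 2.35. In the counted reads this order rested on Mir143, because without the most abundant member of each list the log2 ratio was -0.26. A stretch found in another miRNA gene is held by 3 of 9 measured smooth muscle and mesenchyme members. It is held by 0 of 11 epithelial members. Reads of those 3 members that mapped to several places are not counted, so the value of -0.26 can be too low. The epithelial list exceeded the multiciliated list by 0.76 ± 0.012, or by 2.45 without Mir429 and Mir449a. All of these ratios had the same sign in both pups. No p is given for these ratios, and the smallest that an exact two-sided sign-flip test on 2 libraries can give is 0.5. A list total measures reads, not numbers of cells.

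**Figure D1:**
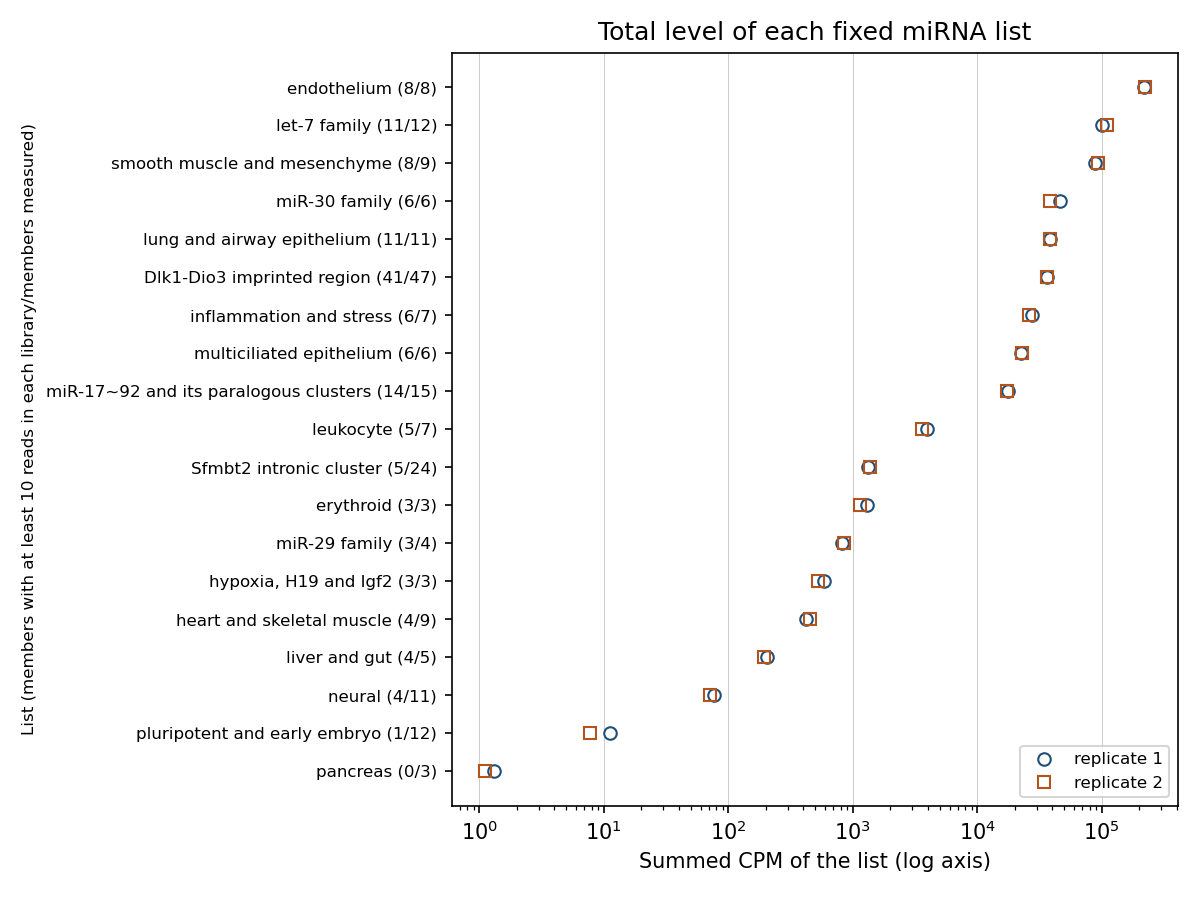
Summed level of each miRNA list in CPM on a log axis, with 1 circle for replicate 1 and 1 square for replicate 2; the numbers beside each name are members with at least 10 reads in each library out of those measured. The totals run from 1.21 CPM for the pancreas list to 220167 CPM for the endothelial list, and the pups differ little beside that range.

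In the counted reads, blood-cell miRNAs were low beside the compartments of the lung wall. The leukocyte list totalled 3763 ± 216 CPM (SD, n = 2), led by Mir342 at 1378 ± 406 CPM, the myeloid miRNA Mir223 at 1307 ± 106 CPM, and Mir146, the row for miR-146a, at 830 ± 116 CPM. The erythroid list totalled 1227 ± 111 CPM, with Mir451a at 890 ± 246 CPM, Mir144 at 322 ± 132 CPM and Mir486 at 15.9 ± 2.81 CPM. The erythroid list lay below the leukocyte list by a log2 ratio of -1.62 ± 0.047, and by -2.88 without Mir451a and Mir342. The inflammation and stress list totalled 26705 ± 932 CPM, of which Mir21a made up 95.02%, and Mir31 stood at 250 ± 8.43 CPM. That list shares the rows of miR-155, miR-146a and miR-146b with the leukocyte list. Reads from the locus of Mir142, a leukocyte miRNA, fell outside the strand counted here and are not in the leukocyte total. A stretch found in another miRNA gene is held by 1 of 3 measured erythroid members, Mir486, and by 2 of 7 leukocyte members. Mir486b has no row. Uncounted reads can leave both totals too low and affect their ratio, which was -1.27 without members that hold such a stretch.

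Among the miRNA families, let-7, whose members accumulate as tissues mature, was far above the growth-associated miR-17 clusters. The let-7 list totalled 105169 ± 6347 CPM (SD, n = 2), led by Mirlet7g with 45.5% of it, Mirlet7i and Mirlet7d. The list of miR-17~92 and its paralogous clusters totalled 17476 ± 184 CPM, led by Mir17 at 5954 ± 562 CPM, Mir106b at 3136 ± 445 CPM and Mir93 at 2790 ± 23.3 CPM. The log2 ratio of the let-7 list to the miR-17 list was 2.59 ± 0.10, a ratio of 6.01. Reads of Mirlet7e and Mirlet7f-1 were not in this total, as their loci were counted only through rows of the other strand. The miR-30 list totalled 42632 ± 5619 CPM, led by Mir30a, Mir30e and Mir30d. The miR-29 list totalled 833 ± 23.3 CPM, led by Mir29a at 725 ± 34.3 CPM and Mir29c at 99.2 ± 7.04 CPM. Mir29b-1 stood at 7.97 ± 3.71 CPM. A stretch found in another miRNA gene is held by 5 of 12 measured let-7 members and 4 of 15 in the miR-17 list. It is held by 2 of 6 in the miR-30 list and 3 of 4 in the miR-29 list. Reads of such members that mapped to several places are not counted. These totals can therefore be too low, and the order of members and the ratio of the lists can be affected.

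Imprinted loci contributed a further share of the reads. The miRNAs of the Dlk1-Dio3 region on chromosome 12, which are expressed from the maternal chromosome, totalled 36207 ± 44.8 CPM (SD, n = 2), and 41 of 47 measured members had at least 10 reads in each library. Mir411 at 6733 and 7036 CPM in replicates 1 and 2, Mir127 at 6737 ± 819 CPM and Mir379 at 4472 ± 210 CPM were the highest of them. Reads at the loci of Mir376a, Mir409, Mir299a and Mir380 lay outside the strand counted and are not in this total. This total exceeded that of the miR-17~92 list by 1.05 ± 0.017 on the log2 scale, a ratio of 2.07. The Sfmbt2 intronic cluster totalled 1348 ± 35.8 CPM, with Mir467e at 466 ± 12.5 CPM, Mir467d at 443 ± 18.2 CPM and Mir467c at 393 ± 8.63 CPM, and 23 of its 24 measured members hold a 20-base stretch found in another miRNA gene. In the list of hypoxia, H19 and Igf2 miRNAs, which totalled 557 ± 45.4 CPM, hypoxia-induced Mir210 stood at 389 ± 21.8 CPM, Mir483 at 147 ± 23.2 CPM and Mir675, within H19, at 20.5 ± 0.329 CPM.

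Markers of organs other than lung were measured to see what a dissected lung held of them. Heart and skeletal muscle miRNAs totalled 437 ± 27.8 CPM (SD, n = 2), mostly Mir208b, in an intron of the myosin gene Myh7, at 299 ± 6.33 CPM and Mir208a, in an intron of Myh6, at 114 ± 14.4 CPM. The muscle miRNA Mir206 stood at 13.0 ± 5.59 CPM. The list lay below the epithelial list by a log2 ratio of -6.46 ± 0.098, or -7.62 without Mir208b and Mir429. Mir1a-1, Mir133a-1 and Mir133a-2, muscle miRNAs with stretches repeated in other miRNA genes, had 0 reads in both libraries, and their levels are uncertain. Such a stretch is held by 4 of 9 measured members of the list, and Mir1a-2 has no row. The list total and both ratios can therefore be too low. Liver and gut miRNAs totalled 200 ± 7.10 CPM, at a log2 ratio of -7.59 ± 0.045 to the epithelial list. They were led by Mir192 at 92.5 ± 6.48 CPM, Mir194-2 with 257 and 235 reads in replicates 1 and 2 and the hepatocyte miRNA Mir122 at 49.5 ± 5.08 CPM. A stretch found in another miRNA gene is held by 2 of 5 measured members, so this total and ratio can also be too low.

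Neural miRNAs totalled 73.8 ± 3.54 CPM (SD, n = 2), with Mir128-1 at 39.4 ± 1.11 CPM, Mir138-2 at 15.5 ± 1.82 CPM and Mir138-1 at 12.5 ± 2.01 CPM. Their log2 ratio to the epithelial list was -9.03 ± 0.063, or -9.62 without Mir128-1 and Mir429, and all 11 measured members hold a stretch found in another miRNA gene. The pluripotent and early embryo list totalled 9.50 ± 2.48 CPM, with Mir294 at 3.74 ± 0.332 CPM, Mir293 at 2.70 ± 1.48 CPM and Mir291a at 0.828 ± 0.389 CPM. The pancreas list totalled 1.21 ± 0.154 CPM, with Mir217 at 6 and 4 reads in replicates 1 and 2, and Mir216a and Mir216b at 0 and 1 read each. By the percentile of the list median among 10000 random lists drawn from all measured genes, 16 of the 19 lists were at or above the 95th percentile in both libraries. Since 1306 of 1973 genes had no read in either library, most random lists have a median of 0. A list with a low median can then pass, as the pluripotent list did at percentiles of 97.6 and 97.7 in replicates 1 and 2. With random lists drawn from genes with at least 10 reads in the libraries together, 4 lists were, namely lung and airway epithelium, endothelium, let-7 and miR-30. That comparison is stricter for lists with undetected members, which stay in the list median while such genes are absent from the random lists.

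Genes that lie together and are transcribed together were then compared within 28 clusters with at least 2 measured members. In 16 clusters the highest member exceeded the lowest by at least 10-fold in both libraries, and in 8 by at least 100-fold. Mir449a exceeded Mir449b, at 9.28 ± 2.17 CPM, by 10.92 ± 0.39 on the log2 scale (SD, n = 2), a ratio of 1943. Mir322 exceeded Mir503 by 6.57 ± 0.061, Mir143 exceeded Mir145a by 5.45 ± 0.088, Mir30d exceeded Mir30b by 5.21 ± 0.19 and Mir34c exceeded Mir34b by 4.94 ± 0.12. None of the members of these clusters holds a 20-base stretch found in another miRNA gene.

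In 11 of those 16 clusters the lowest member did hold such a stretch. Mir17 exceeded Mir19b-1 by 10.02 ± 0.20 on the log2 scale (SD, n = 2), Mir30e exceeded Mir30c-1 by 9.25 ± 0.45, Mir30a exceeded Mir30c-2 by 8.27 ± 0.23, Mir99a exceeded Mirlet7c-1 by 8.16 ± 0.088 and Mir214 exceeded Mir199a-2 by 6.90 ± 0.11. With all members that hold such a stretch left out, 6 clusters kept a range of at least 10-fold. Smaller ranges were seen for Mir200c over Mir141 at 2.55 ± 0.12, Mir106b over Mir25 at 2.71 ± 0.14 and Mir182 over Mir96 at 1.84 ± 0.15. Mir221 over Mir222 stood at 0.84 ± 0.093. Mir15a and Mir16-1 were nearly equal in the counted reads at 0.03 ± 0.14. Mir16-1 holds a stretch found in another miRNA gene and Mir15a does not, so uncounted reads of Mir16-1 can hide a difference. The order of Mir451a and Mir144 was the same in both pups, but the ratio was 4.67 in replicate 1 and 1.72 in replicate 2.

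**Figure D2:**
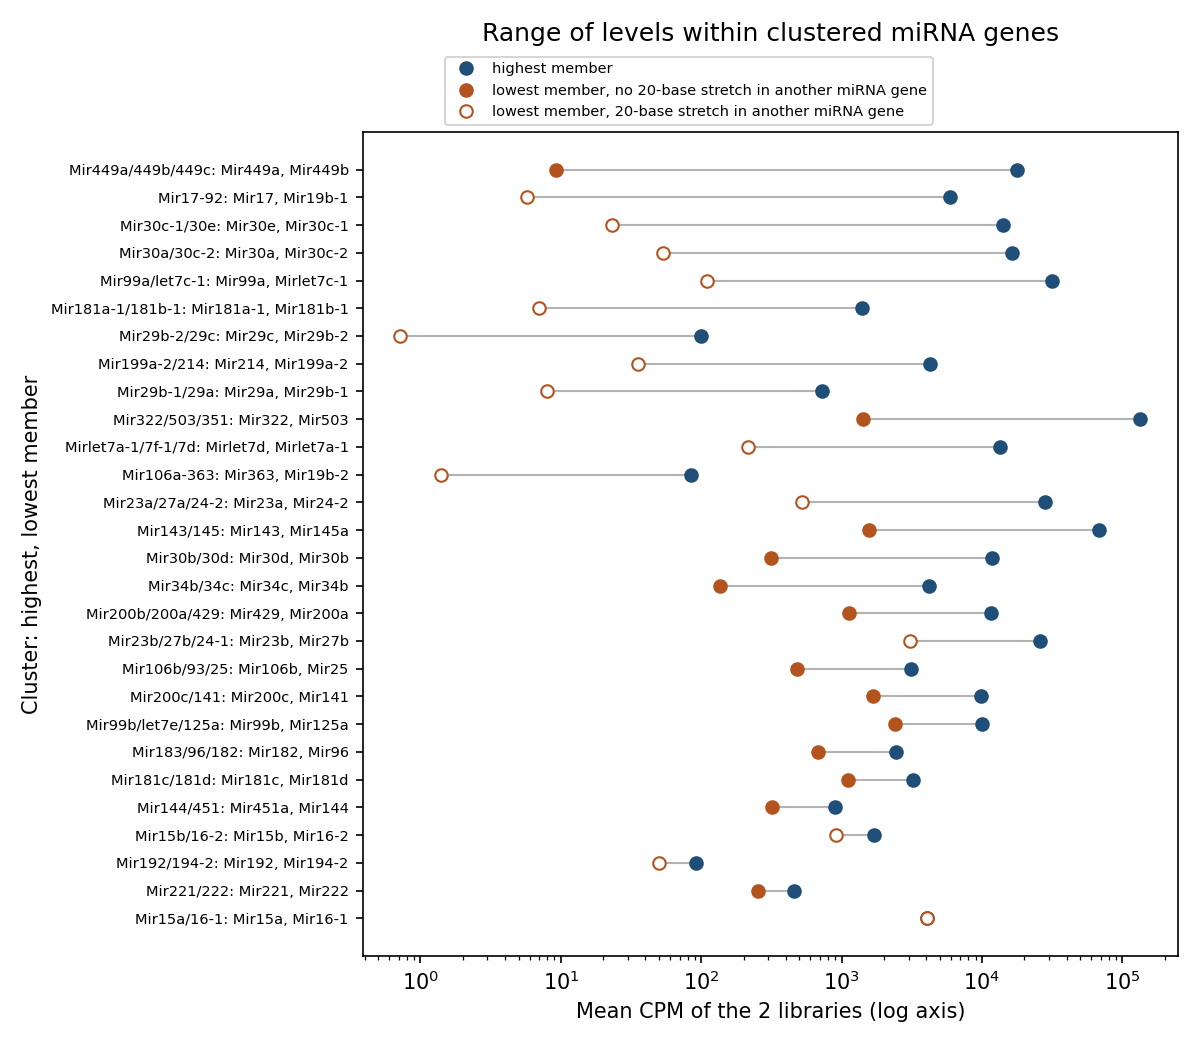
Mean level over the 2 libraries, in CPM on a log axis, of the highest and the lowest member of each of 28 miRNA clusters, joined by a line; open circles are lowest members with a 20-base stretch found in another miRNA gene. The widest gap joins Mir449a at 17777 CPM and Mir449b at 9.28 CPM, and the narrowest joins Mir15a and Mir16-1.

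The profiles of the pups were close. Across the 344 miRNA genes with at least 10 reads in either library, log2(CPM + 1) gave a Pearson r of 0.994 (bootstrap 95% interval 0.991 to 0.996) and a Spearman rho of 0.990 (0.983 to 0.994), both across genes, which are not independent replicates. Mir126a, Mir200c and Mir22 had log2 ratios of replicate 2 to replicate 1 of 0.00, 0.00 and -0.01. With TMM scaling these were 0.070, 0.070 and 0.064, and with DESeq2's size factors 0.054, 0.054 and 0.048. Among the 233 genes with a mean of at least 100 reads, 84.1% lay within 25% of an equal level, and the largest log2 ratio in size was 0.88. The SD of the log2 ratio was 0.26 (0.23 to 0.29), against 0.088 from counting noise alone. The edgeR common dispersion gave a coefficient of variation between libraries of 13.2%.

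Some genes nevertheless differed by more than counting error. Mir144 was higher in replicate 2, with 1033 and 2253 reads in replicates 1 and 2, a log2 ratio of 0.87 and an adjusted p of 1.11e-59 in the two-sided exact binomial test with Benjamini-Hochberg adjustment. Mir490 (0.88, adjusted p 5.03e-05), Mir296 (0.57, 6.30e-46), Mir701 (0.55, 6.04e-06) and Mir700 (0.45, 7.27e-08) in the same exact test completed the 5 highest. On the other side stood Mir423, with 14341 and 9878 reads and a log2 ratio of -0.80 (its p was too small to be represented), Mir668 at -0.85 (adjusted p 5.31e-11, exact), Mir181b-2 at -0.79 (7.26e-74), Mir1981 at -0.67 (0.000166) and Mir667 at -0.65 (1.79e-07). In all, 159 of 375 genes passed, 72 of them higher and 87 lower in replicate 2, so 45.3% were higher. With edgeR's TMM scaling 101 were higher and 61 lower, or 62.3%, and with DESeq2's size factors 93 were higher and 66 lower, or 58.5%.

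Over all tested genes, 42.4% differed. The test allows for counting error only, so genes with more reads pass at smaller ratios. Mir322 passed at a log2 ratio of -0.02 (adjusted p 1.50e-20, exact binomial test). Counts by group therefore depend on read depth and do not rank the groups by how far the pups differed. By group, 3 of the 6 members of the miR-30 list were lower in replicate 2 and none was higher, with 3 differing when adjusted over the list alone. Mir30a, Mir30e and Mir30d had log2 ratios of -0.24, -0.35 and -0.22, or -0.17, -0.28 and -0.15 with TMM scaling. In the lung and airway epithelium list 9 of 11 members differed, and 9 adjusted over the list alone, while its total differed by a log2 ratio of -0.01, which turned to 0.06 with TMM scaling and 0.04 with size factors. In the Dlk1-Dio3 list 24 of 41 tested members differed, and 26 adjusted over the list alone, while its total differed by 0.00, or by 0.07 with TMM scaling and 0.06 with size factors. In the let-7 list 8 of 11 tested members differed, and 9 adjusted over the list alone. In the leukocyte list 5 of 6 differed, and 6 adjusted over the list alone, with Mir342 at -0.61 and Mir223 at 0.17. In the miR-17~92 list 5 of 15 differed in either adjustment, in the endothelial list 5 of 8, and in the smooth muscle list 5 of 8.

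In the inflammation and stress list 4 of 7 tested members differed adjusted over the list alone, and 3 over all genes. In the multiciliated, erythroid, heart and skeletal muscle, liver and gut, miR-29 and hypoxia lists 2 members each differed in either adjustment. Of 5 tested members of the neural list and 6 of the Sfmbt2 list, 0 differed by this exact test, adjusted over all genes or over the list alone, and 0 without adjustment. The highest neural member, Mir128-1, had 175 and 218 reads in replicates 1 and 2, so the 0 neural calls do not show that the pups were alike. Only 1 member of the pancreas list and 2 of the pluripotent list had enough reads to be tested, too few and too low for their 0 calls to show that the pups were alike, and 1 of the pluripotent members passed without adjustment. A difference of at least 2-fold was found for 13 genes, and none of these had a mean of 100 reads or more. These tests compare the 2 libraries, not conditions, and they treat each read as independent.

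**Figure D3:**
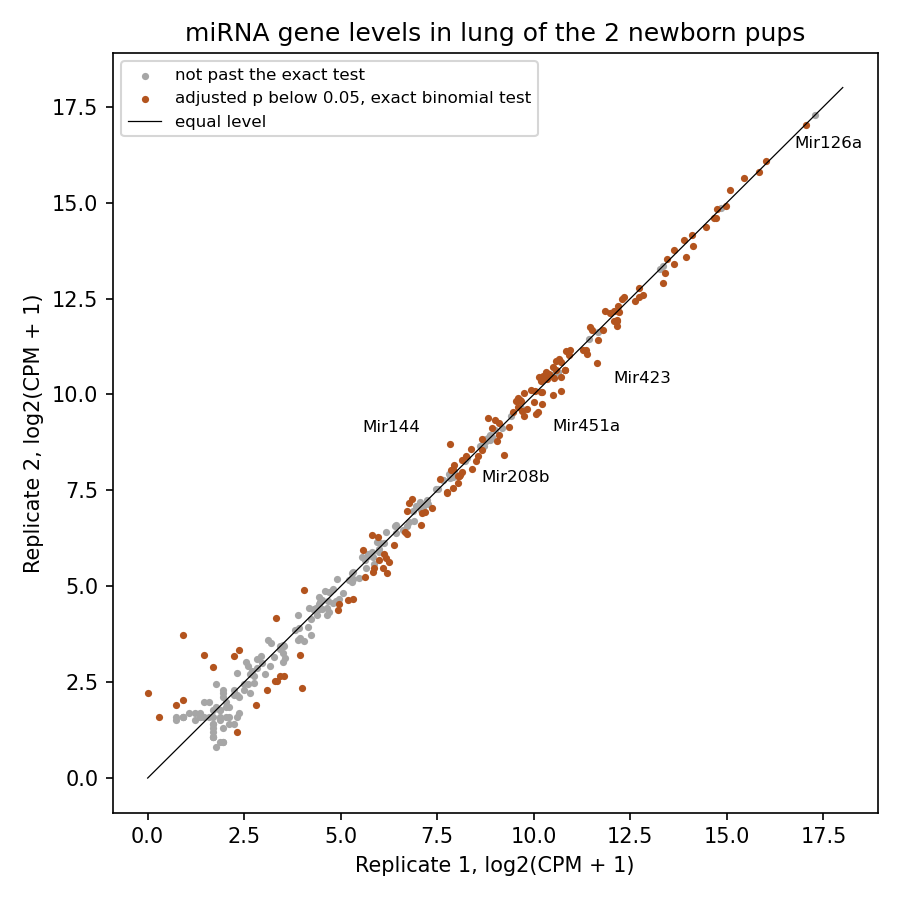
Level of each miRNA gene with at least 10 reads in either library, as log2(CPM + 1), in replicate 1 on the horizontal axis and replicate 2 on the vertical axis; coloured points have an adjusted p under 0.05 in the exact binomial test and the line marks equal levels. Mir144 lies above the line, and Mir423 and Mir451a lie below it.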

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

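The tests of the opposite-strand reads, the cluster members and the red cell miRNAs were chosen only after the results were seen. So was the use of the planned TMM count and of the median log2 ratio for a shift by abundant genes. The test of GC content was set before. The design names a single group and so gives no biological explanation to test, and blood was tested as RNA from other cells in the tissue.

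Reads on the strand opposite to the counted gene form a signal in a column that the comparisons above did not use, with 83568 reads in replicate 1 and 108456 in replicate 2, far above the 3 reads that a count of 0 allows. Of these reads, 99.9% lie in rows that overlap another miRNA gene of GENCODE M21 on the other strand, and 11 rows with at least 100 reads in each library hold nearly all of them. Loss of strand in the libraries is argued against, as the 25 most abundant genes carry 0.000587% of their reads on the opposite strand. A candidate explanation is that these are reads of the partner genes, none of which has a row of its own among those analysed here. By that reading Mir497 would stand at 3155 ± 160 CPM (SD, n = 2), Mir378a at 3040 ± 329 CPM, Mirlet7e at 2952 ± 210 CPM, Mir191 at 2660 ± 12.8 CPM, Mir376a at 1934 ± 111 CPM, Mir142 at 1666 ± 159 CPM, Mir299a at 1539 ± 3.83 CPM and Mir409 at 1535 ± 73.7 CPM.

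Many cluster members lie far below an abundant neighbour. In clusters that hold members with and without a 20-base stretch found in another miRNA gene, those with the stretch lay lower in both libraries in 10 of 11 clusters. The exception was Mir15a and Mir16-1. The median difference over all 11 clusters was -5.97 on the log2 scale. Some of these clusters are paralogs that share a stretch, so they are not independent and no p is given, but loss of reads that match several genes may account for part of the low counts, such as those of Mir30c-1, Mirlet7c-1 and Mir199a-2. It is argued against as the whole cause, because 5 of 13 clusters with no such stretch in any measured member also had a range of at least 10-fold in both libraries, among them Mir449a with Mir449b and Mir322 with Mir503. For those, unequal processing, stability or cloning of the precursors stays open, as do reads lost to copies outside the annotated miRNA genes.

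More genes differed between the libraries than counting error allows, 159 of 375. A shift imposed by a few abundant genes would move the other genes together. It is argued against by a median log2 ratio of -0.013 with totals, over the 233 genes with a mean of at least 100 reads. With TMM scaling 162 genes differed, 135 of them the same, but this count does not decide the question. TMM scaling moved that median to 0.057, away from equal levels, so it took out no shift shared by these genes. GC content of the precursor is argued against by a Spearman rho of -0.0317 with the log2 ratio over 233 genes. After its trend was removed, 99.9% of the SD was left. The GC content of the sequenced reads themselves was not measured, so this covers the precursor only. A change in the amount of blood alone would move Mir451a and Mir144 the same way, but they stood at -0.57 and 0.87 on the log2 scale. Differences between the pups in cell makeup and differences in library preparation stay open, and each pup has 1 library, so these were not separated.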

How the results depend on the processing

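Leaving out members with shared stretches was chosen after the data were examined. The number of genes differing between the libraries was within 1.5 times of 159 under each alternative tried, at most 165. Leaving Mir126a out of the totals changes no ratio between libraries, since its share was equal in both, and so tests nothing here. The coefficient of variation ranged from 11.9% to 13.2%, and the SD of the log2 ratio was 0.26 in the either-strand column too. For the list totals, the mean over 2 libraries hardly responds to a scaling that raises one library and lowers the other, and leaving out either library moves it by a fixed part of its SD, so these settings say nothing about stability. In the either-strand column 13 of the 19 totals stayed within 1 SD and 6 moved by more. This column enlarges the library totals, so every list but leukocyte fell by a small factor, and whether it counted as moved depends on its SD. The leukocyte total rose from 3763 to 5327 CPM. Totals without Mir126a raise every list by about the same factor (18 moved by more than 1 SD), and all 19 moved without their top member.

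With 1 read as the minimum 514 genes were detected. In the either-strand column the top gene took 15.8% and the top 10 took 60.9% of reads, and the erythroid to leukocyte log2 ratio was -2.15, as this column adds the reads at the Mir142 locus. Pearson's r was 0.997 with no minimum, 0.996 with 100 reads, 0.989 with a pseudocount of 0.1 and 0.997 with 10, and Spearman's rho was 0.887 with no minimum and 0.994 with 100 reads. These settings differ in the weight of low-count genes. With random lists from genes with reads, 4 lists passed the 95th percentile.

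Without the top member of each list, the log2 ratios to epithelium were 1.14 for endothelium, -0.26 for mesenchyme (reversed), -7.62 for heart, -9.62 for neural and -7.96 for liver. Let-7 to miR-17~92 was 2.32, Dlk1-Dio3 to miR-17~92 1.35, erythroid to leukocyte -2.88 and epithelium to multiciliated 2.45. These follow from the share of the top member. Values to epithelium can also be too low, as no epithelial member holds a shared stretch. Such a stretch is held by 5 of 8 measured endothelial members, 3 of 9 mesenchyme, 4 of 9 heart, 2 of 5 liver and all 11 neural members. Without members with shared stretches, the ratios were 2.07 for endothelium, -8.02 for liver, -1.27 for erythroid to leukocyte and 0.70 for Dlk1-Dio3, and 6 clusters had a 10-fold range. The neural list has no member left, so it gives no value. Depth limits single genes below about 10 reads, where 0 reads allow 0.662 CPM in replicate 1 for a gene whose reads have a single position.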

Other observations

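The grouping by position was chosen after the profile was seen. Positional groups of miRNA genes, joined on a strand by gaps of up to 10000 bases, held much of the profile. On chromosome X, 7 genes between 53047997 and 53054349 (Mir322, Mir351, Mir503, Mir542, Mir450b, Mir450-2 and Mir450-1) took 14.7% ± 0.347 of reads (SD, n = 2), of which Mir322 gave 13.4% and Mir351 0.898%. On chromosome 12, 34 genes between 109709060 and 109747960, 29 of them detected and led by Mir411, took 2.44% ± 0.0488, and 13 genes between 109563692 and 109595030, led by Mir127, took 1.16% ± 0.0457. Chromosome 12 had 50 detected genes of 117, the most of any chromosome, but 3.95% ± 0.0288 of reads.

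By place in the annotation, miRNA genes in introns took 34.3% ± 0.321 of reads (SD, n = 2), those overlapping exons 30.0% ± 0.312 and those between genes 35.6% ± 0.0086. Host genes of abundant intronic miRNAs included Mest for Mir335, Wdr82 for Mirlet7g, Ctdsp1 for Mir26b and Cdc20b for Mir449a. The detected share was lowest between genes, with 89 of 832, against 138 of 738 in introns and 81 of 324 over exons. Mir208b and Mir208a, hosted by Myh7 and Myh6, had 1337 and 1649 reads and 469 and 672 reads in replicates 1 and 2, so both pups had Mir208b as the higher of the pair.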
